A study of Homo sapiens with 12 samples.

How the data were processed

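Gene expression was measured on 12 Illumina bead arrays of total RNA from 2 breast cancer lines, MDA-MB-231 and BT-549, each with 3 arrays in 10 uM everolimus and 3 in DMSO for 48 h. Per the labels' protocols, RNA was isolated with the mirVana kit, amplified with the TotalPrep kit and stained with streptavidin-Cy3. The deposited value table holds log2 signals of 47230 probes, rounded to 2 decimals. Their log base is inferred from the values: 2 raised to the highest value (14.56) is 24154, within the range of a 16-bit scanner, while e raised to it is 2105370. The authors quantile normalized the deposited log2 values between arrays, as read from the data: all 12 columns have the same quantiles (lowest 6.24, median 6.65). Background was not subtracted to 0 and no probe was centred. The software, the background correction and any filter are not given in the sources used here. 0 pairs of arrays were identical. A second deposited table of unnormalized bead intensity has 12 columns whose names match no sample label, so they were left unmapped and not used here.

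The design written before the data were examined called for normexp background correction and a detection p-value filter. Neither could be run, as the mapped values carry no detection p-values or control probes. The deposited log2 values were used as they stand, with a floor on dim probes in place of the detection filter. The floor was 6.77, the peak of the background (6.55) plus 3 SDs of 0.0724 estimated from the values below the peak. A probe was kept if at least 3 of 12 arrays lay above the floor. This floor was chosen after the distribution of the values was seen and before any test. Because background was left in, fold changes of dim genes are compressed.

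Probes were named from the platform's annotation, which pairs 30113 of the 47230 probes with 1 gene symbol and 8 with several, while 17109 are not listed and stay unnamed. Entrez identifiers of 30074 probes matched the gene name table (assembly GRCh38.p14, used for names only), and 0 symbols had to be updated. Only probes with 1 symbol were used. Above the floor were 15583 probes of 11764 genes. For the 3117 genes with several such probes, the one with the highest mean over all arrays was kept, and the text says where other probes disagree.

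Group means were fitted with limma 3.58.1 (R 4.3.3, statmod 1.5.0) to all 12 arrays, so that the comparisons share 1 estimate of spread per gene (8 residual degrees of freedom, 2.89 added by the empirical Bayes prior). The contrasts, tested 2-sided, were everolimus against DMSO in each line, the difference between these effects, and BT-549 against MDA-MB-231 under DMSO. P-values were adjusted over genes by the Benjamini-Hochberg method for each contrast, and genes were called at an adjusted p under 0.05. Shared genes were those called in both lines in the same direction, beside the number expected of independent lists. Figures were drawn with Python 3.11.15, matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3. Where no probe of a gene reached the floor on any array of 1 of the compared groups, the fold is a lower bound, with the floor in place of lower values.

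Genes named in the text follow a fixed rule. SUV39H1, MTOR and FKBP1A are given whatever their result. In each line the 10 largest rises and 10 largest falls among called genes whose groups do not overlap are named. For the difference between lines and for the baseline, it is the 5 largest each way. For a list it is up to 4 members with the smallest p, or 8 for homologous recombination, and further genes of the shared set are named as such. 36 gene lists were fixed from general knowledge, on DNA repair, replication and the cell cycle, mTOR signalling, metabolism, stress responses, ribosomes and markers of cell types. 35 had at least 4 tested members and were tested with limma's camera (preset correlation between genes of 0.01), with a Benjamini-Hochberg adjustment over lists for each contrast. Beside it stand camera with an estimated correlation and fry, with its own Benjamini-Hochberg adjustment over lists. Members are also counted after adjustment over the list alone.

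Replicate numbers are shared by the groups, and whether to fit them as a block was decided from the correlation of same-numbered arrays' deviations from their group means. In MDA-MB-231 these were r = 0.735, 0.544 and 0.418, all above the limit of 0.1, so the pairing used there comes from the data and not from the labels. Deviations from a group mean sum to 0. With replicate 1 far out in both groups, replicates 2 and 3 tend to correlate whatever their numbers. The limit therefore does not show that numbers 2 and 3 pair. Fits with the replicate number as a block (4 residual degrees of freedom) are given beside results in MDA-MB-231 where they change a call or a count. Arrays 3 of MDA-MB-231 still correlated better with another number (0.546).

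The pipeline was tested on simulated data with the observed means and spreads. In 5 simulations with 200 changed genes per line, limma called 30.1%, 69.9% and 94.5% of genes changed by 0.5, 1 and 2 log2 units in MDA-MB-231. In BT-549 it called 23.9%, 73.1% and 93.0%, and for the difference 10.9%, 55.9% and 87.2%. False calls were 5.41%, 5.95% and 4.77% of all calls. Lists shifted by -0.3 were called in 5 of 5 simulations, also with an estimated correlation, and 0 other lists were called. The noise was drawn independently for each gene and array, with no correlation between genes and no replicate effect. Genes co-vary in the real arrays, so these rates do not show how the tests, above all those of lists, behave on them.

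Other settings written down in advance varied the floor, the choice of probe, each line on its own, the prior, the replicate block, each array left out in turn, a stricter threshold, a minimum of 2-fold and the correlation used by camera. Settings added after the values were seen were subtraction of the background peak, cyclic loess, equal medians of tested genes, a floor at 6 SDs (6.98), leaving out the 4 replicate 1 arrays, each line on its own with the block, and, for the lists of the difference, leaving out members with both group means of a line below the floor. Regroupings of the arrays (10 for a line or the baseline, 100 for the difference and the shared set, and the 31 that part every same-numbered pair, fitted with the block) show how often other splits give as many calls.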

Results

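MDA-MB-231 and BT-549 are established human breast cancer lines of the triple-negative class, which lacks the oestrogen and progesterone receptors and amplified HER2. Each line was kept for 48 h in 10 uM everolimus, an inhibitor of the growth kinase mTOR, or in its vehicle DMSO. Total RNA was read on Illumina bead arrays, with 3 arrays in each of 4 groups (12 arrays). The labels do not say whether replicates are separate cultures, so the p-values measure only the spread between these samples, which may be technical. Of 11764 genes tested, between 9840 and 10360 lay above the background floor on any array. Arrays of the same group correlated at r = 0.927 to 0.995, and the median standard error of a log2 fold change was 0.155. The replicate 1 array lay furthest from its group mean in every group. Its deviations across genes had an SD of 0.246 and 0.271 in MDA-MB-231 (DMSO and everolimus) and 0.229 and 0.393 in BT-549, against 0.0822 to 0.227 on the other 8 arrays. In BT-549 DMSO replicate 3 lay nearly as far from the mean, at 0.218. With changes of 1 log2 unit put into simulated data with independent noise, limma called 69.9% of the changed genes in MDA-MB-231 and 73.1% in BT-549. With 0.5 log2 units it called 30.1% and 23.9%. Signals and fold changes are on the log2 scale, errors of group means are SDs with n = 3, and every adjusted p is from limma with the Benjamini-Hochberg adjustment.

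**Figure D1:**
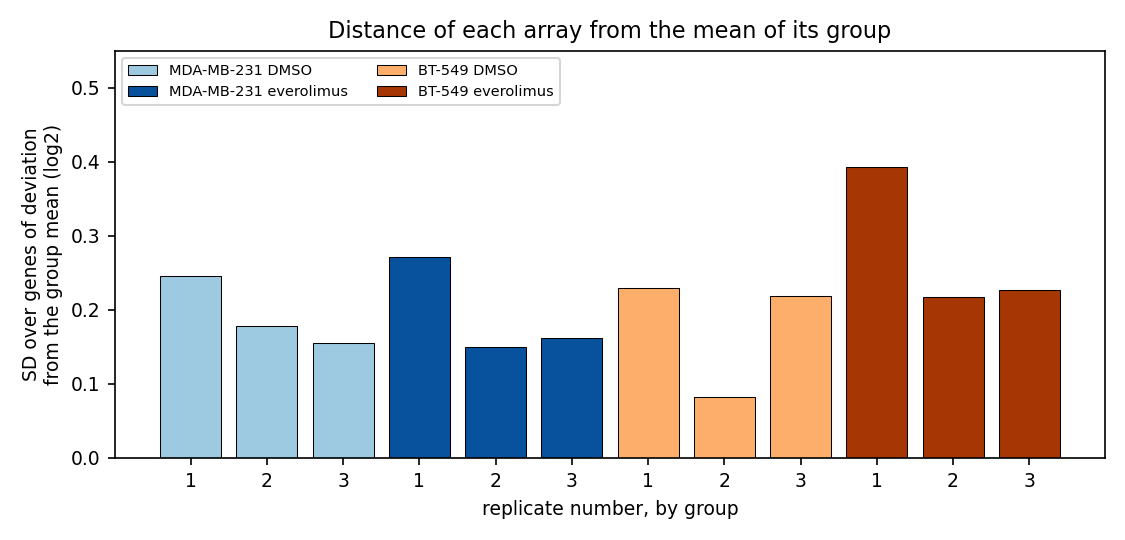
Distance of each array from its group. Bars give the SD across genes of an array's deviation from its group mean, on the log2 scale.

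The series title places SUV39H1, an enzyme that methylates histone H3 lysine 9 in heterochromatin, between mTOR inhibition and homologous recombination. SUV39H1 RNA (probe ILMN_1781479) fell in BT-549 from 8.50 ± 0.07 (SD, n = 3) to 7.44 ± 0.30, a 2.10-fold lower signal (log2 fold change -1.07, SE 0.15, adjusted p = 0.00195). In MDA-MB-231 it was 8.75 ± 0.18 in DMSO and 7.93 ± 0.12 in everolimus, 1.77-fold lower, which missed the threshold (log2 fold change -0.83, adjusted p = 0.0665). With the replicate number as a block it passed (limma adjusted p = 0.0476), though a pairing of all 3 numbers is not shown. It also passed without the BT-549 everolimus replicate 1 array (0.0225), which widens the shared estimate of spread. In both lines the 3 everolimus arrays all lay below the 3 DMSO arrays. The effects were not shown to differ between the lines on all arrays (difference -0.24, adjusted p = 0.623, and 0.472 with the block). Without the 4 replicate 1 arrays, a setting chosen after the values were seen, they were called different (SUV39H1 difference -0.53, adjusted p = 0.0472), and SUV39H1 in MDA-MB-231 was called too (-0.67, 0.012). MTOR (probe ILMN_1769031), the drug's target, was not called in either line (log2 fold change -0.11, adjusted p = 0.965 in MDA-MB-231, and 0.04, 0.944 in BT-549). FKBP1A (probe ILMN_1683658) encodes FKBP12, the protein that everolimus binds. It was not called either (0.09, adjusted p = 0.965, and -0.28, 0.419). With 1 array left out FKBP1A in BT-549 ranged from -0.51 (without DMSO replicate 1) to -0.08 (without DMSO replicate 3), uncalled in 12 of 12 fits. Its 3 other probes gave 0.33, -0.11 and 0.27 in MDA-MB-231 and -0.83, -0.31 and -1.06 in BT-549, so the probes disagree in sign in MDA-MB-231, and in BT-549 all 4 lay below 0 with different sizes.

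**Figure D2:**
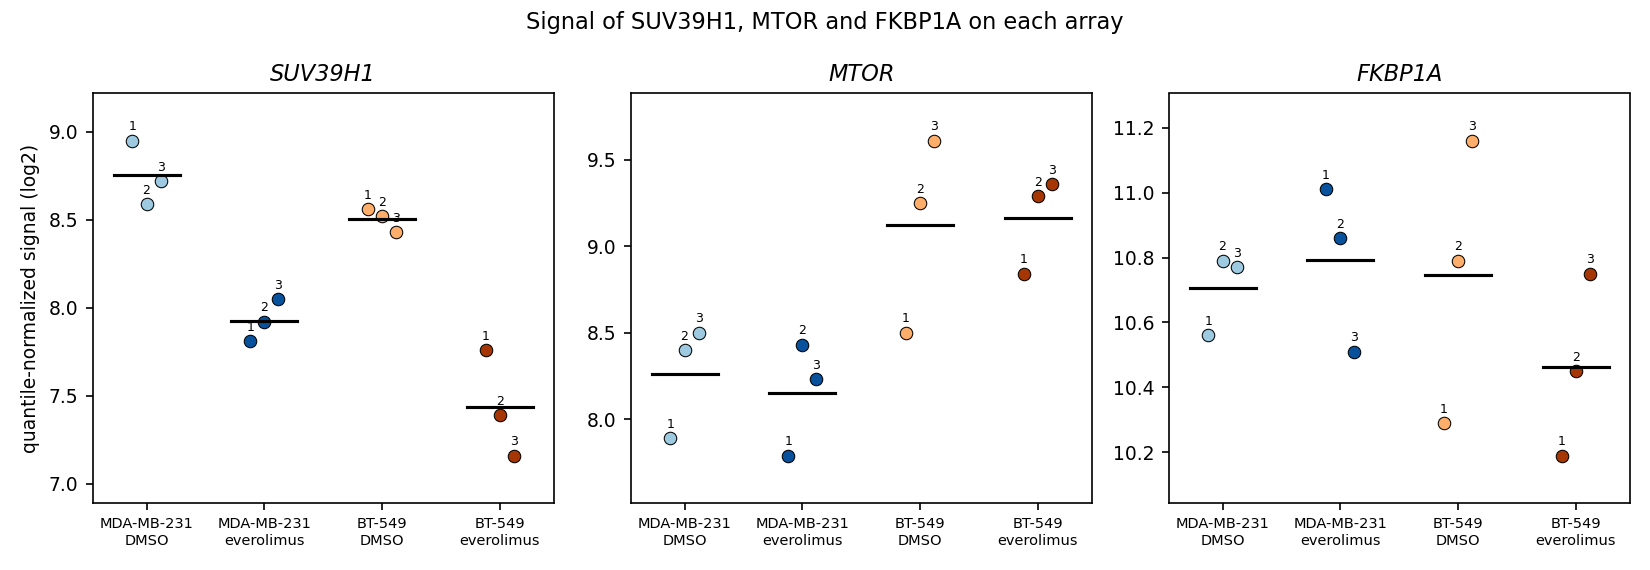
SUV39H1, MTOR and FKBP1A on each array. Points are log2 signals of single arrays and bars are group means. SUV39H1 was called in BT-549, and MTOR and FKBP1A were called in neither line.

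What 48 h of everolimus does to RNA levels in MDA-MB-231 was asked first. The genes that rose included signalling adaptors of growth factor receptors. IRS2, the insulin receptor substrate, rose 1.89-fold and GAB2, a docking protein of receptor tyrosine kinases, 1.91-fold. The transcriptional regulator CREBRF, a negative regulator of the factor CREB3, and KLF13, a Kruppel-like factor, also rose. Among the falls were 2 genes of mitochondrial function, NDUFAF5, an assembly factor of respiratory complex I, and RTN4IP1, a mitochondrial oxidoreductase. In all, 18 of 11764 genes were called, 12 higher and 6 lower, and 3 rose at least 2-fold. At an unadjusted p under 0.05 there were 1246. With the replicate number as a block limma called 79 (39 higher, 40 lower), 15 of them among the 18. Other settings gave 0 on the line's own 6 arrays (limma, 1587 at an unadjusted p under 0.05) and 1044 there with the block. They gave 2 with the background peak subtracted, 6 with a trended robust prior, 11 with the stricter floor, 30 without a floor and 806 without the 4 replicate 1 arrays.

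The largest rise among called genes in MDA-MB-231 was that of ZNF581, a zinc finger gene, from 8.70 ± 0.03 to 10.48 ± 0.53 (log2 fold change 1.77, adjusted p = 0.0229). KLHL24, a substrate adaptor of cullin-3 ubiquitin ligases, rose by 1.27 (0.0497) and the RIO family kinase RIOK3 by 1.02 (0.0229). ZSWIM4 rose by 0.95 (0.0463), although a second probe gave 0.07. GAB2 rose by 0.93 (0.0259), IRS2 by 0.92 (0.0497) and CREBRF by 0.92 (0.023). The non-receptor tyrosine kinase PTK6 rose by 0.89 (0.0229), with 0.17 on another probe. TFPI, the inhibitor of the tissue factor pathway of clotting, rose by 0.82 (0.0337), and KLF13 by 0.74 (0.0463). Among called genes the largest fall was that of NDUFAF5, from 8.88 ± 0.11 to 7.89 ± 0.02 (-0.98, adjusted p = 0.0148). LSM10, a protein of the U7 particle that trims histone messenger RNAs, followed (-0.78, 0.023), then RTN4IP1 (-0.77, 0.0337). NUDT16L1 (-0.61, 0.0497), C19orf53 (-0.51, 0.0495) and UBE2NL (-0.49, 0.0497) completed the 6. These 3 were not called with the block (adjusted p = 0.0504 each), and UBE2NL is a near copy of UBE2N, so its probe is uncertain.

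These counts hung on single arrays. Limma called 0 genes without MDA-MB-231 DMSO replicate 2 or 3 (1112 and 939 at an unadjusted p under 0.05) and 0 without everolimus replicate 2 or 3 (980 and 880), 4 without MDA-MB-231 DMSO replicate 1, 35 without everolimus replicate 1, and 125 without BT-549 everolimus replicate 1. Leaving out the other BT-549 arrays gave 13, 1 and 9 (DMSO replicates 1, 2 and 3) and 9 and 7 (everolimus replicates 2 and 3).

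Among the genes that fell in BT-549 under the same dose were single genes of the matrix, glycolysis, mitochondria and the proteasome. COL1A2, a chain of type I collagen, fell 5.70-fold, and SPARC, a matrix glycoprotein, 3.99-fold. The glycolytic enzyme PGAM1 fell 6.34-fold, PRDX3, a mitochondrial peroxidase, 4.21-fold and PSMC4, an ATPase of the proteasome, 4.28-fold. DDIT4, whose product restrains mTORC1 under stress, fell 7.05-fold. Rises included FST, the secreted antagonist of activin, NPC1, the lysosomal cholesterol exporter, and DUSP5, a nuclear phosphatase of ERK. Limma called 1972 of 11764 genes (16.76%), 1122 higher and 850 lower, with at least 2-fold changes in 236 and 181. At an unadjusted p under 0.05 there were 3720. The balance of rises and falls depends on the scaling: with the medians of the tested genes made equal between arrays it turned to 877 higher and 1088 lower.

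By size, the called rises in BT-549 without overlap of the groups were led by ZNF581, from 9.21 ± 0.25 to 12.24 ± 0.22 (log2 fold change 3.04, adjusted p = 0.00014). FST rose by 2.80 (0.0152; 1.34 on a second probe), the histone gene H2AC25 by 2.43 (0.000252) and NPC1 by 2.31 (0.00355). Histone genes are near copies of each other, so that probe is uncertain. The long non-coding RNA EPB41L4A-AS1 rose by 2.18 (0.000927). SNHG7, a non-coding host of small nucleolar RNAs, also rose by 2.18 (0.0031), with -0.01 and 1.67 on its other probes. WASF2, which drives actin branching, rose by 1.90 (0.00319), DUSP5 by 1.89 (0.0135), CSNK2A2, a catalytic subunit of casein kinase 2, by 1.88 (0.00715) and PPP1R15A, which directs the dephosphorylation of eIF2alpha, by 1.86 (0.00254). EPB41L4A-AS1 was 1.24 higher in MDA-MB-231 too (adjusted p = 0.0856, and 0.0225 with the block).

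The called falls of largest mean size in BT-549, without overlap of the groups, were those of RNA28SN5, DDIT4 and PGAM1, in an order that single arrays change. The signal of RNA28SN5, one of many copies of the 28S ribosomal RNA gene, went from 12.85 ± 0.18 to 9.88 ± 1.80 (-2.98, adjusted p = 0.0131). Another probe gave -1.54, and which copy is read is uncertain. The arrays read amplified RNA, and whether these probes follow the amount of 28S RNA was not tested. With 1 array left out RNA28SN5 ranged from -3.98 (without BT-549 everolimus replicate 1) to -2.26 (without everolimus replicate 3, where DDIT4 and PGAM1 fell further), and its call was kept in 12 of 12 fits (highest adjusted p = 0.048). On the line's own 6 arrays RNA28SN5 was not called (adjusted p = 0.0735), nor with the block. DDIT4 fell from 11.75 ± 1.12 to 8.93 ± 0.27 (-2.82, 0.00262) and PGAM1 from 10.56 ± 0.34 to 7.89 ± 0.41 (-2.66, 0.000301). CA4, a carbonic anhydrase, followed (-2.54, 0.0205), then COL1A2 (-2.51, 0.00139), BEX5 (-2.41, 0.009), PSMC4 (-2.10, 0.00771) and PRDX3 (-2.07, 0.00213). CACYBP fell on its brightest probe (-2.00, 0.00429) and not on its other one (0.22). SPARC fell from 11.59 ± 0.69 to 9.59 ± 0.44 (-2.00, 0.00234). With 1 array left out DDIT4 ranged from -3.44 (without BT-549 DMSO replicate 3) to -2.36 (without DMSO replicate 1), called in 12 of 12 fits. CA4 kept its call in 8 of 12 fits, FST in 9 and DUSP5 in 10 (highest adjusted p = 0.0842, 0.0645 and 0.0584). Those losses came without BT-549 DMSO replicate 1 (CA4), DMSO replicate 2 (all 3), everolimus replicate 2 (CA4 and FST) and everolimus replicate 3 (all 3). The count of 1972 became 1231 without BT-549 DMSO replicate 1, 795 without DMSO replicate 2, 3289 without everolimus replicate 1, 1204 without everolimus replicate 2 and 860 without everolimus replicate 3.

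A change found in both lines is less tied to the genetic background of either. Limma called 11 genes in the same direction in both. The rises were COQ8A (needed for coenzyme Q), CREBRF, IRS2, KLF13, KLHL24, RIOK3, ZNF581 and ZSWIM4, 8 genes against 1.145 expected of independent lists. The falls were LSM10, NDUFAF5 and RTN4IP1, 3 against 0.4335. Both contrasts use the same estimate of spread per gene, which can favour the same genes in both lists. These expected numbers may therefore be too low, and the excess over them does not by itself show a shared effect. TFPI went opposite ways, up by 0.82 in MDA-MB-231 and down in BT-549 (-0.53, adjusted p = 0.0142). Across all genes the 2 effects correlated (Pearson r = 0.368, Spearman rho = 0.330), with r = 0.225 without MDA-MB-231 DMSO replicate 1. With the replicate block limma called 47 genes in both lines in the same direction. Of the 1972 genes called in BT-549, 1465 (74.29%) had the same sign in MDA-MB-231, against 59.8% of all genes. The 11 became 0 without MDA-MB-231 DMSO replicate 2 or 3 or everolimus replicate 2 or 3. They became 3 and 20 without MDA-MB-231 replicate 1 (DMSO and everolimus), 1 and 7 without BT-549 DMSO replicates 2 and 3, and 71, 7 and 5 without BT-549 everolimus replicates 1, 2 and 3. In the analysis of each line on its own 6 arrays limma found 0 shared genes, and 596 at an unadjusted p under 0.05 in both.

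**Figure D3:**
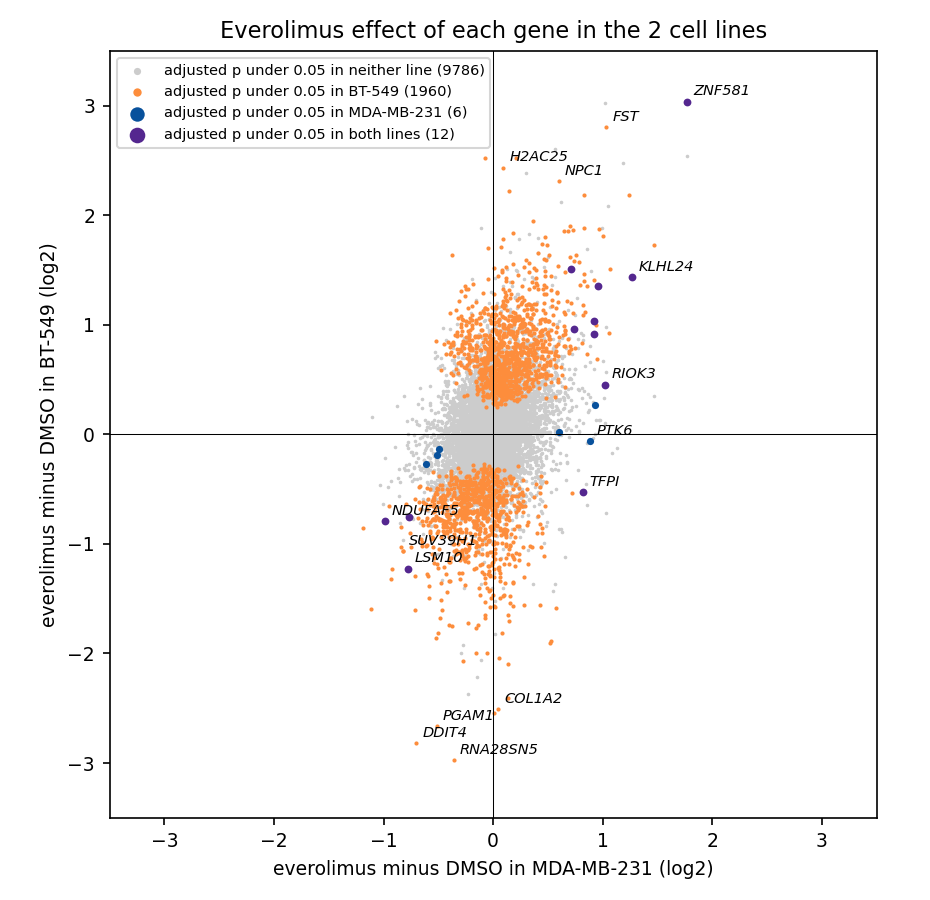
Everolimus effect in BT-549 against that in MDA-MB-231. Each point is a gene, as log2 fold changes against DMSO. Colours separate genes called in both lines, in 1 line and in neither, and some of the genes in the text are named.

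Homologous recombination rebuilds broken chromosomes from the sister copy, and its loss makes cells sensitive to PARP inhibitors, which is the reason to look at its genes here. As a list of 30 tested genes it was not called in either line. In MDA-MB-231 the median log2 fold change was -0.04 (camera adjusted p = 0.625). Limma called 0 members over all genes, 2 at an unadjusted p under 0.05, and 1 when adjusted over the list alone. That gene was SFR1, with 0.67 (adjusted p = 0.101 over all genes, 0.0403 with the block, and 0.07 on another probe). With the block limma called 1 member higher, and without the 4 replicate 1 arrays 1 higher and 2 lower. The next members by p-value, none called, were RAD51C (-0.56, adjusted p = 0.285, and 0.0934 with the block), XRCC2 (-0.36, 0.475), SWI5 (0.25, 0.53), BARD1, the partner of BRCA1 (-0.50, 0.557), RAD54B (-0.27, 0.63), EXO1, a nuclease of end resection (-0.78, 0.701), and RPA1 (-0.30, 0.714).

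In BT-549 single genes of the pathway moved both ways around a list median of 0.05 and a mean of -0.02 (camera direction down, adjusted p = 0.80). Of the 30 tested, limma called 2 higher and 4 lower, the same numbers as over the list alone. It called 3 higher and 5 lower with the block, and 8 higher and 6 lower without the 4 replicate 1 arrays. Of all 11764 genes it called 1972 (16.76%) in BT-549, with 3282 in the block fit and 4498 without those arrays. Calls were thus common in this line, and those of members do not by themselves set the pathway apart. XRCC2 rose by 0.84 (adjusted p = 0.0084), though its other probe gave -0.02, and the nuclease gene MUS81 by 0.70 (0.0121). SEM1, a BRCA2 binding protein that is also a proteasome subunit, fell (-0.79, 0.00334), as did RAD51C (-0.78, 0.0186), the MRN complex gene NBN (-0.56, 0.0225) and RAD54B (-0.62, 0.0261). Other probes gave -0.32 and 0.09 for RAD51C and 0.30 for NBN. With 1 array left out RAD51C and RAD54B kept their calls in 9 of 12 fits and NBN in 8 (highest adjusted p = 0.0728, 0.0875 and 0.0881). All 3 lost them without BT-549 DMSO replicate 2 or 3 or everolimus replicate 3, and NBN also without everolimus replicate 2. MUS81 lost its call without BT-549 DMSO replicate 2 (0.0549). SWI5 (0.36, adjusted p = 0.0721) and HELQ (0.35, 0.0953) were not called. With 1 array left out HELQ ranged from 0.20 (without BT-549 DMSO replicate 1) to 0.46 (without DMSO replicate 3). It stayed uncalled in 11 of 12 fits (lowest adjusted p = 0.0368).

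**Figure D4:**
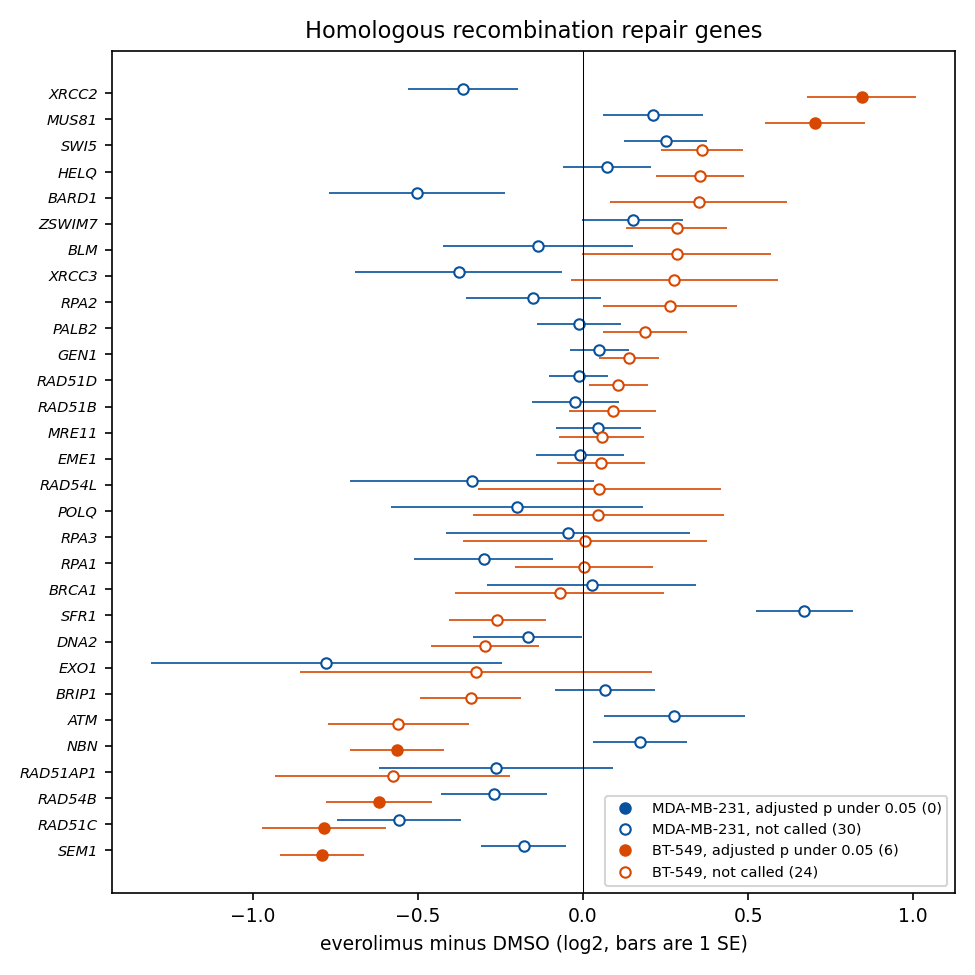
Homologous recombination genes under everolimus. Points are log2 fold changes against DMSO with standard errors, per gene and line, filled for called genes. As a list the genes were called in neither line.

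Other DNA repair lists were not called in either line. The calls of list members in BT-549 stand beside 16.76% of all genes called there. The Fanconi anaemia list (11 tested) had medians of 0.03 in MDA-MB-231 and -0.05 in BT-549, with 2 members higher and 1 lower in BT-549. End joining (11) had -0.10 and 0.15 (1 higher), and base excision repair (17) -0.09 and -0.08 (3 higher, 1 lower). Mismatch repair (4) had -0.14 and -0.19 (2 lower), and checkpoint kinases (13) -0.10 and 0.02 (1 higher, 1 lower). Limma called 0 members of these 5 in MDA-MB-231, with 3, 0, 1, 0 and 2 at an unadjusted p under 0.05. Histone lysine methyltransferases and heterochromatin genes (19) had -0.10 and 0.11, with camera adjusted p = 0.0945 and 0.878. Components of the mTOR pathway (25) had -0.003 and 0.13 (adjusted p = 0.842 and 0.878), with 6 members higher and 3 lower in BT-549.

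In MDA-MB-231 the lists called lower hold genes for ribosome assembly, DNA copying, amino acid supply and respiration. Those called higher hold genes of lysosomes, growth factor receptors, inflammation and cell cycle exit. Camera called 8 of 35 lists, and 0 with an estimated correlation between genes (2 at an unadjusted p under 0.05). Fry, a rotation test of each list by itself, called 2, oxidative phosphorylation and the FOXO list (adjusted p = 0.0305 each). Oxidative phosphorylation (38 tested) had a median of -0.22 and 34 members below 0 (adjusted p = 6.29e-06, adjusted p = 0.186 with an estimated correlation). Limma called 0 members over all genes (8 at an unadjusted p under 0.05) and 5 over the list alone. Ribosome biogenesis (24) had a median of -0.37 (adjusted p = 1.64e-05, adjusted p = 0.619 with an estimated correlation). Its 0 calls over all genes stand beside 8 unadjusted and 1 over the list alone, with NOP56, a core protein of box C/D particles, at -0.90 (adjusted p = 0.118). DNA replication (31) had -0.23 (0.00651, adjusted p = 0.79 with an estimated correlation), with 0 members called, 2 unadjusted and 1 over the list alone. ATF4 targets (30), which serve amino acid supply, had -0.15 (0.0315, adjusted p = 0.744 with an estimated correlation), with 0 members called, 3 unadjusted and 0 over the list alone. PSAT1, an enzyme of serine synthesis, had -1.11 (adjusted p = 0.135). The ATF4 list kept its call in 9 of 12 fits with 1 array left out, and without MDA-MB-231 everolimus replicate 1 its median was -0.08 (camera adjusted p = 0.283). It also lost the call without MDA-MB-231 DMSO replicate 2 or 3.

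Among the higher lists in MDA-MB-231, FOXO targets and receptor tyrosine kinases (22) had a median of 0.12 (camera adjusted p = 0.00739, adjusted p = 0.186 with an estimated correlation). IRS2 was called, and 4 members over the list alone. TXNIP, which curbs glucose uptake, had 1.47 (adjusted p = 0.128, and 0.0338 with the block). Lysosome and autophagy genes (33) had 0.21 (0.00628, adjusted p = 0.619 with an estimated correlation), with 0 members called, 9 unadjusted and 2 over the list alone. With 1 array left out the median of this list ranged over 0.07 to 0.28, and without MDA-MB-231 DMSO replicate 1, which gave the 0.07, its call was lost (adjusted p = 0.0891). ULK1, the kinase that starts autophagy, had 0.88 (adjusted p = 0.0862, and 0.0393 with the block). CDK inhibitors and quiescence genes (13) had 0.43 (0.00902, adjusted p = 0.619 with an estimated correlation), with 0 members called, 5 unadjusted and 3 over the list alone. CCNG2, an atypical cyclin tied to cell cycle arrest, had 0.92 (0.182). Targets of NF-kB and inflammatory factors (25) had 0.37 (0.00902, adjusted p = 0.711 with an estimated correlation), with 0 members called, 1 unadjusted and 1 over the list alone. With the block limma called 0 members of this list higher and 1 lower, against the direction of the list. The cytokine IL24 had 1.47 (0.0895). Without MDA-MB-231 DMSO replicate 3 the NF-kB list had 0.24 and lost its call (adjusted p = 0.114).

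With the replicate number as a block camera called 13 lists in MDA-MB-231. The 5 added were G1/S regulators (18; median -0.18, adjusted p = 0.0713 without and 0.00831 with the block), fatty acid synthesis (13; -0.24, 0.0679 and 0.0227) and the heat shock response (15; -0.17, 0.0713 and 0.0308). Interferon-stimulated genes (30; 0.15, 0.12 and 0.014) and basal markers (5; 0.29, 0.12 and 0.0115) were the others. In the fit without a block, camera with an estimated correlation gave these lists adjusted p = 0.768, 0.744, 0.775, 0.815 and 0.619, in this order. Without MDA-MB-231 everolimus replicate 2 the 8 lists of the fit without a block became 13.

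**Figure D5:**
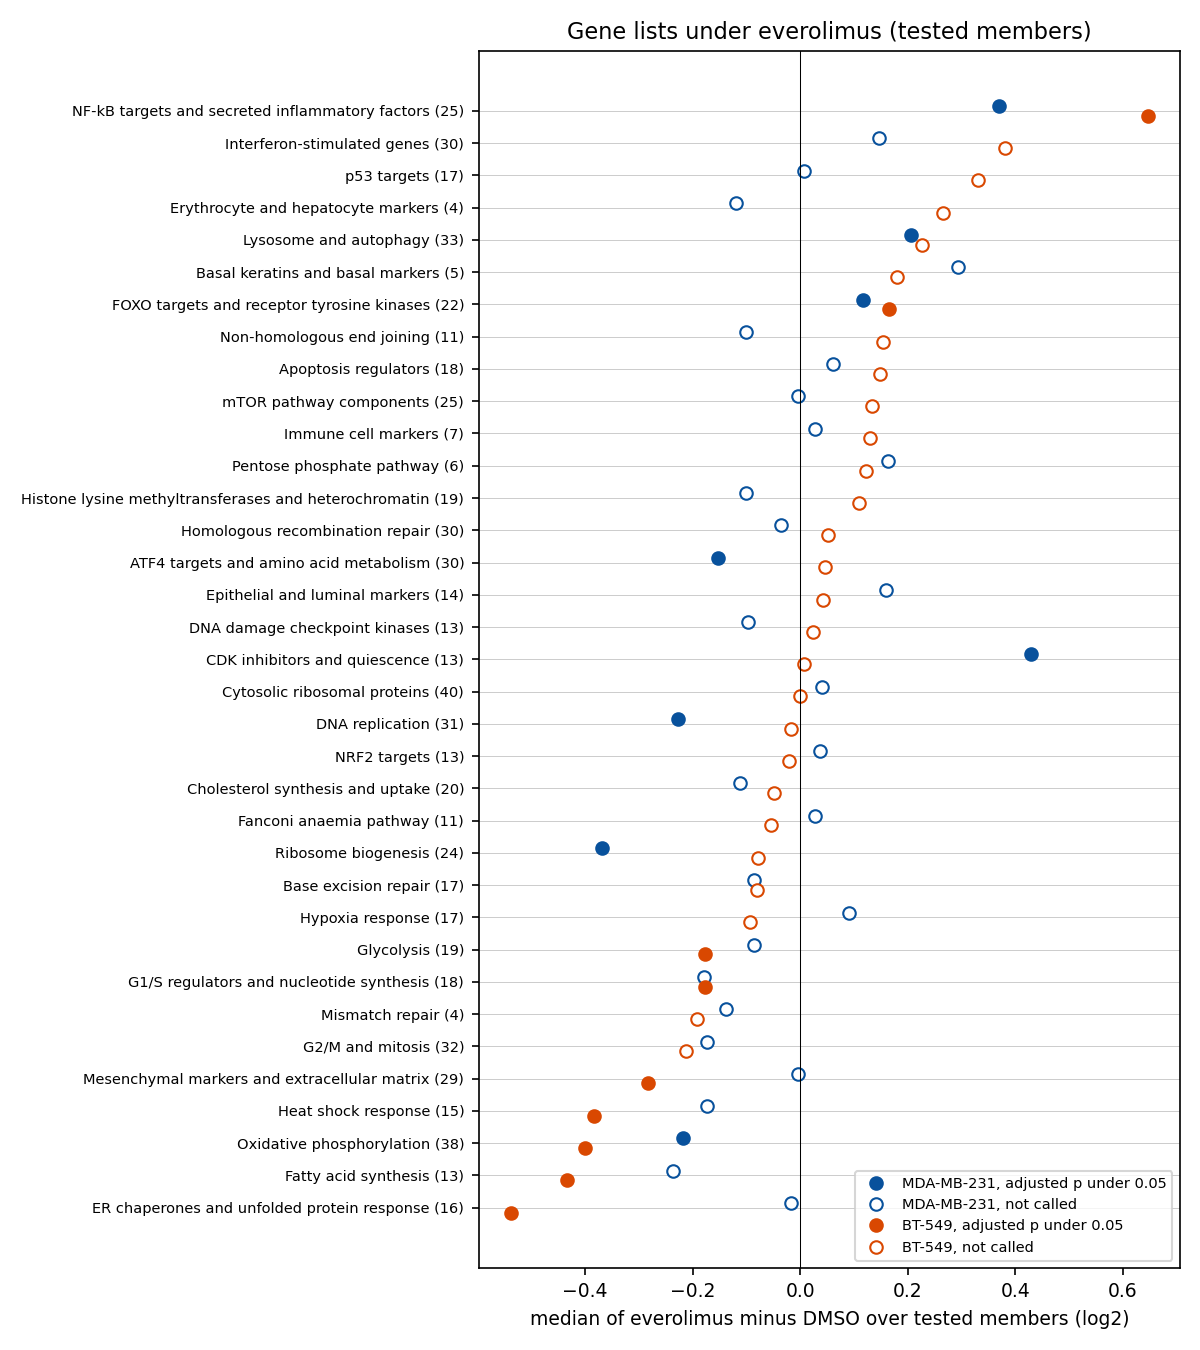
Gene lists under everolimus. Points are the median log2 fold change over tested members in each line, filled for lists called by camera. With an estimated correlation between genes camera called no list in either line.

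In BT-549 the lists called lower hold genes of mitochondrial respiration, of protein folding in the endoplasmic reticulum and cytosol, of matrix and of carbon metabolism. Camera called 9 of 35 lists, and 0 with an estimated correlation (3 at an unadjusted p under 0.05). Of 10 splits of the 6 BT-549 arrays, the real one among them, 6 called at least 9 lists. The median of the other splits was also 9, so the number of lists does not tell the treatment from other groupings. Fry called 4: oxidative phosphorylation (adjusted p = 0.00028), FOXO targets (0.00127), mesenchymal and matrix genes (0.00989) and ER chaperones (0.0206). Oxidative phosphorylation had a median of -0.40 (adjusted p = 2.61e-10, adjusted p = 0.0855 with an estimated correlation), with 16 members lower, 0 higher and 22 not called, and 20 lower over the list alone. COX6C and COX5B, subunits of cytochrome c oxidase, fell (-0.80, adjusted p = 0.000771, and -0.89, 0.00278), and UQCRB of complex III fell on its brightest probe (-1.34, 0.000252), with -0.13 and 0.01 on the others. ER chaperones (16) had -0.54 (0.000452, adjusted p = 0.468 with an estimated correlation), with 7 lower, and 2 higher and 9 lower over the list alone. The secreted ER protein MANF fell (-1.08, 0.00962), as did the disulfide isomerase gene PDIA6 (-1.58, 0.0169), whose call was lost without BT-549 DMSO replicate 1 or 2 or everolimus replicate 2 or 3 (highest adjusted p = 0.0671). Without BT-549 everolimus replicate 1 the median of the ER list was -0.33, still called. The heat shock response had -0.38 (0.00755, adjusted p = 0.81 with an estimated correlation), with 6 lower (7 over the list alone), among them the mitochondrial co-chaperone HSPE1 (-1.37, 0.00194) and BAG3 (-0.85, 0.00227). The heat shock median was -0.24 without BT-549 DMSO replicate 3, also still called. Mesenchymal and matrix genes (29) had -0.28 (0.0443, adjusted p = 0.398 with an estimated correlation), with 8 lower, and 1 higher and 8 lower over the list alone. COL1A1 fell from 10.42 ± 0.66 to 8.77 ± 0.07 (-1.65, 0.00231). With 1 array left out the matrix list kept its call in 7 of 12 fits, and its median was -0.14 without BT-549 DMSO replicate 3.

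Glycolysis (19) had a median of -0.18 in BT-549 (camera adjusted p = 0.0443, adjusted p = 0.81 with an estimated correlation), with 3 members lower, and 2 higher and 6 lower over the list alone. LDHA, which turns pyruvate into lactate, fell from 13.19 ± 0.03 to 11.83 ± 0.15 (-1.36, 0.00034), and PGK1 fell too (-1.31, 0.00198). Fatty acid synthesis had -0.43 (0.0443, adjusted p = 0.815 with an estimated correlation), with 0 members called by limma, 4 unadjusted and 0 over the list alone. G1/S regulators had -0.18 (0.0458, adjusted p = 0.815 with an estimated correlation), with 1 higher (CAD) and 3 lower, and 1 and 4 over the list alone. CDK2, a kinase of S phase entry, fell (-1.18, 0.000301), as did SKP2, which targets the inhibitor p27 for destruction (-1.32, 0.00242), with -1.05 and -0.29 on its other probes, and RRM2, a subunit of ribonucleotide reductase (-1.27, 0.0107). FOXO targets and receptor tyrosine kinases had 0.17 (0.0443, adjusted p = 0.389 with an estimated correlation), with 4 higher (5 over the list alone). TXNIP rose by 1.73 (0.00962), KLF6 by 1.12 (0.00538) and FOXO3 by 1.05 (0.00612), although a second FOXO3 probe gave 0.03. NF-kB targets had 0.65 (0.0443, adjusted p = 0.815 with an estimated correlation), with 4 higher and 8 over the list alone, RELB by 1.85 (0.012) and NFKB2 by 1.62 (0.0281) among them. NFKB2 lost its call without BT-549 DMSO replicate 1 or 2 or everolimus replicate 2 or 3 (highest adjusted p = 0.112), CAD without DMSO replicate 1 or everolimus replicate 3 (0.0566) and RELB without everolimus replicate 3 (0.0527). With 1 array left out, G1/S regulators kept their call in 7 of 12 fits, with medians from -0.42 (without BT-549 DMSO replicate 1) to -0.03 (without BT-549 everolimus replicate 1, adjusted p = 0.565). NF-kB targets kept theirs in 5 of 12, with 0.28 without BT-549 everolimus replicate 3. FOXO targets, fatty acid synthesis and glycolysis kept theirs in 6 of 12 each (highest adjusted p = 0.126, 0.129 and 0.128), and the glycolysis median was -0.33 without BT-549 DMSO replicate 3. Leaving out any of the 6 BT-549 arrays, or either replicate 1 array of MDA-MB-231, ended the call of at least 1 of these 5 lists. The 9 lists became 3 without MDA-MB-231 DMSO or everolimus replicate 1 or BT-549 DMSO replicate 2, 6 without BT-549 DMSO replicate 3 and 5 without BT-549 everolimus replicate 2.

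Lists called in neither line, with their medians in MDA-MB-231 and BT-549, were G2/M and mitosis (32; -0.17 and -0.21), cholesterol synthesis (20; -0.11 and -0.05), the pentose phosphate pathway (6; 0.16 and 0.12) and the hypoxia response (17; 0.09 and -0.09). Cytosolic ribosomal proteins (40) had 0.04 and 0.00, p53 targets (17) 0.01 and 0.33, apoptosis regulators (18) 0.06 and 0.15, and NRF2 targets (13) 0.04 and -0.02. Interferon-stimulated genes had 0.38 and basal markers 0.18 in BT-549. Without the 4 replicate 1 arrays the BT-549 medians of G2/M and mitosis and of the hypoxia response turned to 0.16 and 0.09 (camera adjusted p = 0.727 and 0.772). Camera then also called p53 targets (0.0373), interferon-stimulated genes (0.0103), ribosome biogenesis (0.0317) and lysosome and autophagy (0.0479) in BT-549, and no longer G1/S regulators (0.281), fatty acid synthesis (0.0637) and glycolysis (0.362). In MDA-MB-231 it also called interferon-stimulated genes (0.0153), epithelial and luminal markers (0.0117), basal markers (0.00545) and G1/S regulators (0.0012), and no longer ATF4 targets (0.0952). The lists for other cell types were also not called. Epithelial and luminal markers (14) had 0.16 and 0.04, immune cell markers (7) 0.03 and 0.13, and markers of erythrocytes and hepatocytes (4) -0.12 and 0.27. Of the 3 endothelial markers above the floor, too few for camera, limma called 0 in either line, with 0 and 1 at an unadjusted p under 0.05. Lists called in 1 line had, in the other, medians of -0.02 (ER chaperones), -0.003 (mesenchymal and matrix), -0.09 (glycolysis), -0.24 (fatty acid synthesis), -0.18 (G1/S regulators) and -0.17 (heat shock response) in MDA-MB-231. In BT-549 they had -0.08 (ribosome biogenesis), -0.02 (DNA replication), 0.05 (ATF4 targets), 0.23 (lysosome and autophagy) and 0.01 (CDK inhibitors).

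Whether the drug acts differently in the 2 lines is a question for the interaction, the BT-549 effect minus the MDA-MB-231 effect. The single genes with a lower effect in BT-549 include those of a collagen chain, a glycolytic enzyme and a lamin, while the glycolysis list was not called for the difference (camera adjusted p = 0.202). COL1A2 had a difference of -2.55 (adjusted p = 0.0448), but its MDA-MB-231 signal lay at the floor, where a fall cannot be seen. PGAM1 had -2.15 (0.0392; -0.52 in MDA-MB-231), LMNB1, the gene for lamin B1, -1.61 (0.0269; -1.68 in BT-549 and -0.07 in MDA-MB-231), HM13 -1.84 (0.0392) and TMEM14A -1.60 (0.0448). A second HM13 probe gave 0.35 in BT-549. In the other direction were H2AC25 (2.34, 0.0257), CITED4, a coactivator of CBP and p300 (1.66, 0.015), the guidance cue SLIT2 (1.52, 0.0269), NKD2, a Wnt antagonist (1.51, 0.0432), and ARHGAP39 (1.47, 0.0392). H2AC25 and NKD2 lay at or near the floor in MDA-MB-231. Limma called 75 genes, 37 higher and 38 lower, 22 and 26 of them by at least 2-fold, and 1842 at an unadjusted p under 0.05. With the replicate block it called 707, all 75 among them. With the background peak subtracted limma called 0 (1793 at an unadjusted p under 0.05), with a trended robust prior 16, with the stricter floor 24, with every probe on its own 120, and without the 4 replicate 1 arrays 2345. With equal medians it called 23 higher and 42 lower.

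Camera called 3 lists for the difference, each lower in BT-549, and 0 with an estimated correlation (4 at an unadjusted p under 0.05). Of 100 regroupings of the arrays, the real one among them, 90 called at least 3 lists. Fry called 0 (5 at an unadjusted p under 0.05, lowest adjusted p = 0.122). ER chaperones had a median difference of -0.64 (adjusted p = 1.43e-05, adjusted p = 0.304 with an estimated correlation), with 0 members called by limma, 8 unadjusted and 3 over the list alone. Oxidative phosphorylation had -0.19 (0.000214, adjusted p = 0.304 with an estimated correlation), with UQCRB called and 5 over the list alone. Mesenchymal and matrix genes had -0.31 (0.00243, adjusted p = 0.304 with an estimated correlation), with COL1A2 called and 5 over the list alone. Of its 29 members 10 lay below the floor in both groups of MDA-MB-231, where a fall cannot be seen. With the 11 members below the floor in either line left out, a setting chosen after the values were seen, the 18 left had a median difference of -0.34 and the list lost its call (camera adjusted p = 0.0597). The homologous recombination list was not called (median difference 0.11, mean 0.07, camera direction down, adjusted p = 0.849), with 0 members called, 7 unadjusted, and 1 higher and 3 lower over the list alone. The 75 became 0 without MDA-MB-231 DMSO replicate 2 or 3, everolimus replicate 2 or 3, or BT-549 DMSO replicate 2 (1493, 1458, 1496, 1613 and 1419 unadjusted). The 3 lists became 9 without MDA-MB-231 everolimus replicate 1, 7 without BT-549 DMSO replicate 3 and 5 without BT-549 everolimus replicate 1. The genes became 31 without MDA-MB-231 everolimus replicate 1, 11 without BT-549 DMSO replicate 1, and 1219, 16 and 2 without BT-549 everolimus replicates 1, 2 and 3.

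The single genes with the largest differences between the lines under DMSO are given here, and no gene list was tested for this contrast. BT-549 had more RNA for the contractile and mesenchymal proteins smooth muscle actin (ACTA2), beta-tropomyosin (TPM2) and N-cadherin (CDH2), for the matrix protein MGP and for CDKN2A, the locus of the inhibitor p16. MDA-MB-231 had more RNA of the SPANX family, genes normally read in sperm. Limma called 3576 of 11764 genes (30.4%), 1757 higher and 1819 lower in BT-549, with at least 2-fold differences in 593 and 553. MGP was at least 94.3-fold higher in BT-549 (13.33 ± 0.53, adjusted p = 4e-07), CDKN2A at least 37.95-fold (12.01 ± 0.48, 1.7e-07) and CDH2 at least 36.5-fold (11.96 ± 0.14, 1.03e-09), each below the floor in MDA-MB-231. ACTA2 was 72.5-fold higher (13.36 ± 0.83, 0.000139) and TPM2 41.55-fold (13.92 ± 0.32, 6.68e-07). SPANXA2 was at least 109.9-fold lower in BT-549 (13.55 ± 0.30 in MDA-MB-231, 1.28e-08), SPANXD at least 78.0-fold and SPANXC at least 51.25-fold (13.05 ± 0.27 and 12.45 ± 0.66). SPANXB1 and SPANXA1 were 108.9-fold and 98.4-fold lower, with BT-549 near the floor. The SPANX genes are near copies, so which of them is read is uncertain.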

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

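Chosen after the result was seen were the test on the other line's genes in the replicate 1 arrays, the comparison of spreads between the lines, the fit of each line on its own with the block, the regroupings fitted with the block, the counts without the replicate 1 arrays and every value from fits without those 4 arrays. The difference of the everolimus effects between the lines was called for 75 genes by limma and for 3 lists by camera. Named genes with a higher effect in BT-549 were H2AC25 (2.34), CITED4 (1.66), SLIT2 (1.52), NKD2 (1.51) and ARHGAP39 (1.47). Lower effects in BT-549 were those of COL1A2 (-2.55), PGAM1 (-2.15), HM13 (-1.84), LMNB1 (-1.61), TMEM14A (-1.60), PGK1 (-1.37), TFPI (-1.35), CDK2 (-1.08), PTK6 (-0.95) and UQCRB (-0.94). For HM13 and UQCRB other probes do not show the fall in BT-549 (0.35, and -0.13 and 0.01). COL1A2 lay at the floor in MDA-MB-231, where a fall cannot be seen. H2AC25 and NKD2 lay at or near the floor in MDA-MB-231 and PTK6 in BT-549, and what the low baseline adds to these differences was not tested. Without the 4 replicate 1 arrays all 75 genes were called again, among 2345. That fit reuses the remaining arrays and leaves out those furthest from their group means, so it is no separate support for the 75. With 1 array left out in turn the count ranged from 0 to 1219.

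Other splits of the arrays bear on these counts. For the difference, 6 of 100 regroupings gave at least the real 75 genes, the highest other 564, so chance is not excluded. Of the 7 regroupings that left the BT-549 groups whole, 5 gave as many, and they carry the whole BT-549 effect, while the 92 that broke them up gave at most 2. For the lists of the difference, 90 of 100 gave at least the real 3 (highest other 13), so chance is not excluded. With the replicate block the difference had 707 genes, and the highest of the other 30 regroupings that part every same-numbered pair had 669. Only 7 of these 31 called any gene in either line, too few for a share under 0.05. For the shared genes (11, and 47 with the block) the highest other was 0 in both sets, but only the real 1 of 100, and 1 of 31, called any gene in MDA-MB-231 and BT-549 together, so these regroupings decide nothing about sharing. With 10 splits of 6 arrays a share under 0.05 cannot be reached. The real split was the 1 of 10 with most genes in MDA-MB-231 (18, highest other 1, and 0 among the 3 others that part all 3 pairs), the 1 of 10 in BT-549 (1972, highest other 484) and the 1 of 10 between the lines (3576, highest other 0). The 484 came from setting BT-549 DMSO replicates 1 and 2 with everolimus replicate 1 against the rest. For lists, 2 of 10 gave at least 8 in MDA-MB-231 (highest other 8) and 6 of 10 gave at least 9 in BT-549 (highest other 13). Splits that mix the treatments call as many lists, which points to co-varying genes in these arrays.

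The replicate 1 arrays lay furthest from the group mean in every group. In BT-549 DMSO replicate 3 lay nearly as far (SD of deviations 0.218 against 0.229). Replicate 1 thus stood apart from replicates 2 and 3 only in the other groups. A failed or swapped treatment is argued against by the effect in replicate 1, which correlated at r = 0.493 or more with the mean effect of the others. RNA of the other line is argued against by genes off in a line and at least 3 log2 units higher in the other: they rose by a median of 0 in MDA-MB-231 (25 genes) and -0.04 in BT-549 (10 genes), where a 2 percent share would give 0.28 and 0.30. These genes lie at the floor. Over 5350 genes the slope on the other line was -0.126 in BT-549, the wrong way for mixing. In MDA-MB-231 it was 0.107, the way that mixing would give, so the case against mixing there rests on its 25 genes alone. A bend in signal response stays open: cyclic loess left the correlation between the 2 replicate 1 arrays of MDA-MB-231 at 0.9996 of its value, but after quantile normalization it moved their values by an SD of at most 0.105 of that of their deviations, too little for a test. A separate day or batch for the replicate 1 arrays, or a different state of those cultures, may be the source and was not tested, as the labels give neither.

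Fewer genes were called in MDA-MB-231 (18) than in BT-549 (1972), and the size of this gap depends on the fit: with the replicate block limma called 79 and 3282 over all arrays, and 1044 and 1565 with each line on its own. A larger spread in MDA-MB-231 is argued against, as its median residual SD was 0.876 times that in BT-549 (0.161 and 0.184). The replicate 1 arrays alone are argued against too, since without them BT-549 still had 5.58 times as many called genes (4498 and 806, and 4316 and 581 with the block). A smaller effect remains open and has the value it needs: the covariance of effects between replicate pairs was 0.259 times as large (0.0441, range 0.0362 to 0.0537, against 0.170, range 0.126 to 0.256). MDA-MB-231 may respond less at this dose and time, but uptake or growth of the lines was not measured here.

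The oxidative phosphorylation list (38 genes) had a median below 0 in both lines (-0.22 and -0.40), with 0 members called by limma in MDA-MB-231 (8 at an unadjusted p under 0.05) and 16 lower in BT-549, and camera called it in both with the preset correlation but not with an estimated one (adjusted p = 0.186 and 0.0855), while fry did (0.0305 and 0.00028). A normalization bend that lowers abundant transcripts is argued against, as at most 0.29% of 10000 random lists matched on mean signal had a median as low (0.29% in MDA-MB-231, 0.02% in BT-549). The replicate 1 arrays alone are argued against, as without them the medians were -0.22 and -0.52. A lower output of mitochondrial genes under mTOR inhibition and a slower growth of the treated cells both stay open, and neither was tested. A single dose of a single drug was given, so mTOR inhibition cannot be told apart from any other effect of everolimus here.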

How the results depend on the processing

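Chosen after the values were seen were subtraction of the background peak, cyclic loess, equal medians, the stricter floor, leaving out the first-numbered arrays, each line on its own with the replicate block, and leaving members below the floor in a line out of the lists. Counts are of called genes in MDA-MB-231 (18), in BT-549 (1972), for the difference (75), between the lines (3576) and shared (11), and of called lists (8, 9 and 3 for the difference). For each change in this part the cause was not tested.

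Without a floor 30 genes were called in MDA-MB-231 and 18 shared. The mean of probes gave 5 lists for the difference. Every probe on its own gave 120 for the difference, 14 lists in MDA-MB-231 and 6 for the difference. Each line on its own 6 arrays gave 0 in MDA-MB-231 (limma, 1587 at an unadjusted p under 0.05), 1165 in BT-549, 0 shared (596 unadjusted in both), and 13 and 3 lists. A trended robust prior gave 6, 16 for the difference and 3 shared. At an adjusted p under 0.01 limma called 0 in MDA-MB-231 (1246 unadjusted), 601 in BT-549, 0 for the difference (1842), 2070 between the lines and 0 shared (579). At least 2-fold were 3, 417, 48, 1146 and 2. Camera with an estimated correlation called 0 lists in each comparison (2, 3 and 4 unadjusted).

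With the replicate block limma called 79 in MDA-MB-231, 3282 in BT-549, 707 for the difference and 47 shared, and camera 13 lists in MDA-MB-231 and 5 for the difference. In BT-549 the numbers share only a label: same-numbered arrays correlated at 0.50, 0.0787 and 0.411, and replicate 2 correlated better with another number. Replicate 3 of MDA-MB-231 did so too (0.546), so in neither line is a pairing of all 3 numbers shown. These are hints from the data and not the design. In BT-549 FOXO targets lost their call (adjusted p = 0.0746). Beyond the changes given here and in the report, it changed no other call of a named gene or list in MDA-MB-231. Each line on its own with the block gave 1044 in MDA-MB-231, 267 shared and 15 lists in MDA-MB-231.

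Subtracting the background peak gave 2 in MDA-MB-231, 0 for the difference (1793 unadjusted) and 2 shared. Equal medians gave 4 lists in BT-549, and the split of calls moved from 1122 higher and 850 lower to 877 and 1088 in BT-549, and from 37 and 38 to 23 and 42 for the difference. The stricter floor gave 11 in MDA-MB-231 and 24 for the difference. Without the first-numbered arrays limma called 806, 4498, 2345 for the difference and 431 shared, and camera 7 lists for the difference, and the SUV39H1 difference was called (-0.53, adjusted p = 0.0472). Without members below the floor in a line camera called 2 lists for the difference, with the mesenchymal and matrix list lost (0.0597). Cyclic loess moved none of these counts by over 1.5 times.

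Leaving out each array in turn gave 0 to 125 in MDA-MB-231, 795 to 3289 in BT-549, 0 to 1219 for the difference, 2546 to 4400 between the lines and 0 to 71 shared. Lists ranged over 6 to 13 in MDA-MB-231, 3 to 9 in BT-549 and 3 to 9 for the difference. SUV39H1 in MDA-MB-231 ranged over -0.91 to -0.73 (adjusted p = 0.0225 to 0.242), and in BT-549 over -1.23 to -0.93 (0.000195 to 0.0131). Its difference ranged over -0.40 to -0.10 (0.168 to 0.904).

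Directions that reversed belong to uncalled results. MTOR in BT-549 (0.04) was -0.027 with equal medians, -0.11 without the first-numbered arrays and -0.27 to 0.29 with arrays left out. MTOR in MDA-MB-231 (-0.11) ranged over -0.30 to 0.067. FKBP1A in MDA-MB-231 (0.09) was -0.10 without the first-numbered arrays and -0.022 to 0.23 with arrays left out. The homologous recombination median in BT-549 (0.05, with a test direction down) was 0.13 without the first-numbered arrays, with the test up, and -0.10 to 0.19 with arrays left out. The BT-549 medians of G2/M and mitosis (-0.21) and of the hypoxia response (-0.09) were 0.16 and 0.09 without the first-numbered arrays. Over all settings, 1821 of 2254 calls of named genes were kept, 433 lost and 109 gained, and 412 of 497 calls of lists were kept and 85 lost.

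Settings planned before the data were seen that could not be run on the deposited values were quantile normalization without background correction, a median shift and cyclic loess after normexp, a detection p under 0.01 and the chip as a block. The authors' deposited table, planned as a second source, became the source of every result.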

Other observations

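Every gene family here was chosen after the fold changes were seen, as were the values without the replicate 1 arrays and under the other scalings, while the test of small nucleolar RNA hosts without SNHG7 was set before its result. A test of such a family on the same values would not be independent, so medians and counts are given without one, beside the shares of all genes that limma called in BT-549 (9.54% higher, 7.22% lower). Mitochondrial ribosomal proteins (76 tested) had a median of -0.19 in MDA-MB-231, with 69 below 0, and -0.35 in BT-549, with 3 called higher and 24 lower (31.6%). MRPL47 (-1.75, adjusted p = 0.000927), MRPL52 (-1.02, 0.0021) and MRPS7 (-0.78, 0.00195) fell in BT-549. Proteasome subunits (33) had -0.29 and -0.40, with 0 called by limma in MDA-MB-231 and 12 lower in BT-549 (36.4%), such as PSMD1 (-0.91, 0.00154). These signs were the same after cyclic loess, with equal medians (-0.42 and -0.47 in BT-549) and with the background peak subtracted.

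Histone genes (39, those of the histone clusters and the H1 series) had a median of 0.28 in BT-549, with 35 above 0, where 54.8% of all genes lay above 0. The arrays read amplified RNA, and whether these signals follow the amount of histone RNA was not tested. Limma called 4 of them (10.3%), close to the 9.54% of all genes called higher there: H2AC25, H2AC8 (1.40, adjusted p = 0.0157), H1-10, a gene outside the clusters (1.04, 0.0172), and H2AC4 (0.64, 0.00166). In MDA-MB-231 the median was -0.03, and whether the lines differ here was not tested. With equal medians the histone median in BT-549 was 0.21, and without the replicate 1 arrays it was 0.50 with 21 called higher among 4498 genes called there.

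Zinc finger genes named ZNF (312) had a median of 0.13 in BT-549, with 53 called higher (17.0%) and 3 lower, and -0.01 in MDA-MB-231. ZNF706 (1.37, adjusted p = 0.000449) and ZNF16 (1.19, 0.0102) rose beside ZNF581. With equal medians the BT-549 median was 0.06, so its size depends on the scaling. KLF transcription factors (11) had 0.25 in MDA-MB-231 and 0.08 in BT-549, where KLF2 (1.95, 0.03), KLF5 (1.09, 0.0307), KLF6 and KLF13 rose and 5 members lay below 0. With equal medians the BT-549 median was 0.01. Dual specificity phosphatases (18) had 0.13 in MDA-MB-231 and 0.15 in BT-549, where limma called 5 higher and DUSP14 lower (-0.76, 0.00672), with DUSP6 (1.43, 0.00166) rising beside DUSP5. With equal medians the BT-549 median was 0.08. Chaperonin subunits (9) had -0.26 and -0.06, collagens (21) -0.04 and -0.09, and antisense transcripts (66) -0.01 and 0.06. With equal medians these were -0.13, -0.16 and -0.01 in BT-549.

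Hosts of small nucleolar RNAs can rise when translation is blocked, since many are degraded as they are translated, which led to a test of this class. Without SNHG7, whose rise prompted it, the 15 tested hosts had a median of 0.20 in BT-549, above 92.7% of 10000 random lists matched on mean signal and short of the 99% asked for. In MDA-MB-231 it was 0.06, above 94.2%. A shared rise of the class was therefore not shown. In BT-549 limma called 6 hosts higher (37.5% of the 16 with SNHG7) and 1 lower: SNHG32 (1.17, adjusted p = 0.000927), SNHG1 (1.05, 0.0079), SNHG8 (1.03, 0.0174), ZFAS1 (0.93, 0.00424) and SNHG6 (0.76, 0.00697) rose beside SNHG7, and SNHG10 fell (-0.62, 0.0332). With SNHG7 included the 16 hosts had 0.30.

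Groups did not overlap for 2184 genes (18.57%) in MDA-MB-231, 3842 (32.66%) in BT-549 and 5635 (47.9%) between the lines. For 3 against 3 arrays 10% is the average over all splits. Genes co-vary in these arrays, so a single split can lie above 10% by chance. The share in other splits was not counted, so an excess over chance is not shown. In MDA-MB-231 the 18.57% stands beside 18 called genes and 1246 at an unadjusted p under 0.05. The 79 called with the replicate block and the 806 without the replicate 1 arrays leave open that many small changes lie under the spread between replicates. They do not show that these are real. The block rests on a pairing not shown for all numbers. The replicate 1 arrays were left out after they were seen to lie furthest from their group means, which lowers the spread. All 18 were among the 806 with the same sign, but both fits use the same remaining arrays, so this is no separate support.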
